A study of Drosophila melanogaster with 2 samples.

How the data were processed

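The series measured polyA RNA of Drosophila melanogaster larvae on 2 two-colour arrays. Each array compared the same 2 transgenic crosses: GMR crossed to GFP-dASF/SF2, and GMR crossed to GFP-NLS as the control. On array 1 the control RNA carried Cy3 and the dASF/SF2 RNA Cy5, and on array 2 the dyes were swapped, per the labels. The labels do not say whether the RNA of the 2 arrays came from separate extracts or larvae. The p-values of single probes and genes therefore measure the spread between these 2 arrays, which may be technical. Set tests at a preset correlation and permutation tests compare genes or probes with one another. Their p-values do not measure the spread between arrays or larvae. The number of arrays, 2, limits the precision, and the fits have 1 residual degree of freedom.

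The deposited table holds 1 log ratio of the 2 channels per probe and array, for 15744 probes. The scanner, the background correction, the normalization of the deposited log ratios, the filter behind blank cells, the log base and the channel in the numerator are not given in the sources used here. Blank cells numbered 3996 on array 1 and 1450 on array 2, and 7 further cells held the code -10000; both were treated as missing. The deposited column medians were -0.008 on array 1 and 0.007 on array 2. Values were present on both arrays for 11604 probes, on array 1 alone for 139, on array 2 alone for 2688 and on neither for 1313. No other column of values was present, so 0 columns were left unused. The platform annotation gives 1 gene symbol for 13147 probes, several for 99 and none for 2498. Symbols were updated through gene identifiers of the reference table of the Release 6 plus ISO1 MT assembly for 12519 probes, and the annotation's own symbol was kept for 628. Genes were named from probes with 1 symbol, and no coordinates were taken from the reference.

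In the order of the probe numbers, 40 places carried an unnamed feature in each of the 24 blocks of 656 probes, 960 features in all. Features of this kind were treated as control spots and left out of centring and tests, which left 10912 probes measured on both arrays. They were recognised by missing gene names and by place, not by value, but the decision was made after the data had been seen, and the counts with these features kept are given in the closing section.

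Choices fixed before the data were examined were the reading of direction, the tests and the gene lists. The deposited values were read as Cy5 over Cy3 on both arrays, so the sign of array 2 was turned. A fixed exception, in which SF2 had to reach 0.5 in absolute value with the same deposited sign on both arrays, did not apply. Each array was centred on its median. A positive value then means a higher level in dASF/SF2 larvae if the deposited ratio is Cy5 over Cy3, and a lower level if it is Cy3 over Cy5. The sources used here do not settle this, so signs are given as the positive and the negative side, and only the separation of the sides is fixed. All signed values also depend on the deposited values running by dye, and the other reading, in which they already run by genotype, was computed for the counts, the agreement of the arrays, the spread, SF2, the genes of the naming rule and the tests and medians of the lists; the random lists, the tests of symbol families and the comparison of tissue lists used the turned values alone. The log base was set to 2 beforehand. Because the files do not name it, values are printed on the deposited scale, and folds are given for base 2 and for base 10. Test statistics do not depend on the base.

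Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, against 0), with Benjamini-Hochberg adjusted p under 0.05. Values are held to 3 decimals in the table, and the prior degrees of freedom of eBayes moved from 4.35 in the reported fit to 5.69 without centring. They were 3.43 with the values read as already running by genotype and 8.85 with named probes centred on all features. The lowest adjusted p by limma was 0.419 in the reported fit, and 0.981 and 0.0384 in these 2 alternatives. Size was counted without a model, as probes at least 2-fold or 1.5-fold from the median on both arrays, on the same side or on opposite sides. Gene-level values were means over the probes of a gene (9266 genes). Lists of genes were tested with camera at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over 21 lists. At this setting camera compares the genes of a list with the other genes, so its p-values do not measure agreement between arrays. The lists were tested again with an estimated correlation and with fry. These tests rest on 1 residual degree of freedom and had little power, so a call lost there cannot decide whether a list shifted. A list needed at least 3 measured members. The position of a list's median among 10000 random lists of the same size was also computed; no expression levels were in the table, so these lists were not matched on level. The 21 lists were SR proteins, hnRNP proteins, core spliceosome, retinal determination, photoreceptor specification, phototransduction, apoptosis, stress and heat shock, antimicrobial response, cell cycle and DNA replication, cytosolic ribosomal proteins, oxidative phosphorylation, ecdysone response, and markers or products of muscle, fat body, salivary gland, midgut digestion, cuticle, neurons, hemocytes and testis.

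The rule for named genes took SF2, the 12 genes per side with the highest value of the smaller of both arrays' absolute values, any gene called by limma, the 2 highest and 2 lowest members of each list, w, Yp1, Yp2, Yp3, roX1 and roX2, and 3 genes with high values of opposite sign. Both fits were tested on simulated data. With the 10912 probes and the spread of these arrays, limma was run on 10 simulated data sets. It called 12.4% of 659 probes changed by 0.5 in deposited units, 92.0% of 665 changed by 1 and 99.9% of 676 changed by 2. False calls averaged 14.9 per data set. The 82, 612 and 675 correct calls are sums over all 10 sets, so the 14.9 cannot be set against them as an error share. These shares hold for the planted changes and do not give the power in the reported data. In the reported fit, CG6271 at -0.986 had an adjusted p of 0.419 by limma. The set test, at an unadjusted p under 0.05, called 98% of 200 lists of 20 genes shifted by 0.15. Of 200 lists without a shift it called 0.5%. These genes were simulated as independent, with a fixed spread not taken from the arrays. The shares therefore do not describe the adjusted calls of the real lists.

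Alternatives planned beforehand were the other reading of direction, no centring, arrays scaled to equal spread, quantile normalization, each array alone, probes with an exact 0 left out, a robust variance prior, a plain t statistic, other thresholds, gene-level means, other set tests and another choice of probe per gene. Alternatives chosen after seeing the data kept the repeated unnamed features, used named probes alone, added probes measured on 1 array, read the values as log10 or natural log, and corrected for place in the probe order. That correction laid each block out in rows of 16 and subtracted the median of the neighbours up to 2 rows and columns away, with at least 5 neighbours required.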

Results

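Transcriptome-wide log ratios were obtained from 2 arrays in a dye swap, each setting larvae that carried GFP-tagged dASF/SF2 against larvae that carried GFP with a nuclear localisation signal. dASF/SF2, encoded by SF2 (CG6987), is an SR protein, a family of RNA-binding proteins that act in pre-mRNA splicing. GMR is an enhancer active in the developing eye. The comparison addresses whether gene expression differs broadly between these larvae. A group of 2 arrays was formed, each giving 1 ratio of dASF/SF2 larvae to control larvae. Values below are means of both arrays ± SD (n = 2) on the deposited log scale, after the second array was turned. The log base and the overall sign are not settled, so folds are given for base 2 and base 10 and directions as the positive and negative side.

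The probe for SF2 itself lay near 0, at -0.031 on array 1 and -0.128 on array 2. Its mean of -0.0795 ± 0.0686 (SD, n = 2) had a 95% interval of -0.325 to 0.166, and limma gave an adjusted p of 0.999. The size corresponds to 1.06-fold on base 2 or 1.20-fold on base 10. The sources used here do not say whether this probe lies in a part of the transcript that the transgene carries or how much of the RNA came from eye tissue, so the value does not check the labels. Among the yolk protein genes, Yp1 had a mean of 0.0305 and Yp3 of -0.043, and these values do not show the sex mix of the larvae. No value on both arrays under a single symbol was present for w, Yp2, roX1 or roX2.

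Of the 12 genes with the strongest values on the negative side, 6 were digestive enzymes of the midgut list. CG6271 (-0.986 ± 0.070, SD, n = 2) stood lowest of the 12, at 1.98-fold on base 2 or 9.67-fold on base 10. The trypsins epsilonTry (CG18681, -0.864 ± 0.198) and betaTry (CG18211, -0.709 ± 0.190) and the Jonah proteases Jon65Aiii (CG6483, -0.689 ± 0.026), Jon25Biii (CG8871, -0.704 ± 0.156), Jon25Bii (CG8869, -0.612 ± 0.038) and Jon65Aiv (CG6467, -0.585 ± 0.006) are the list members. The others were yip7 (CG6457, -0.693 ± 0.117), Muc18B (CG7876, -0.671 ± 0.005), CG10912 (-0.679 ± 0.057), CG31789 (-0.634 ± 0.050) and CG6277 (-0.631 ± 0.097). None of these genes was called by limma, with adjusted p from 0.419 to 0.438 over the 24 strongest genes of both sides.

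The 12 genes with the strongest values on the positive side held 1 member of the cuticle list and 0 of the muscle and midgut lists. They included hlk (CG9432, 0.794 ± 0.061), CG12896 (0.841 ± 0.149), sona (CG9850, 0.695 ± 0.004), yellow-d2 (CG9891, 0.654 ± 0.013) and Ank (CG1651, 0.699 ± 0.086). Actn (CG4376), which encodes alpha-actinin of the muscle Z-disc, had 0.658 ± 0.038 on 1 of its 2 probes and 0.194 on the other. SERCA (CG3725), the calcium pump of the sarcoplasmic reticulum, had 0.613 ± 0.052 on the named probe, while its 3 other probes gave 0.486, 0.359 and -0.0905. The tyrosine hydroxylase gene ple (CG10118, 0.717 ± 0.123), which supplies dopamine for cuticle tanning as well as for neurons, the glycolytic phosphoglycerate mutase gene Pglym78 (CG1721, 0.661 ± 0.084), the larval cuticle gene Lcp65Aa (CG7287, 0.646 ± 0.090) and CG32241 (0.612 ± 0.030) followed. CG8319 had the highest mean of the 12, 1.23 ± 0.885, but its arrays differed widely at 0.608 and 1.86. A value of 0.794 corresponds to 1.73-fold on base 2 or 6.22-fold on base 10.

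**Figure D1:**
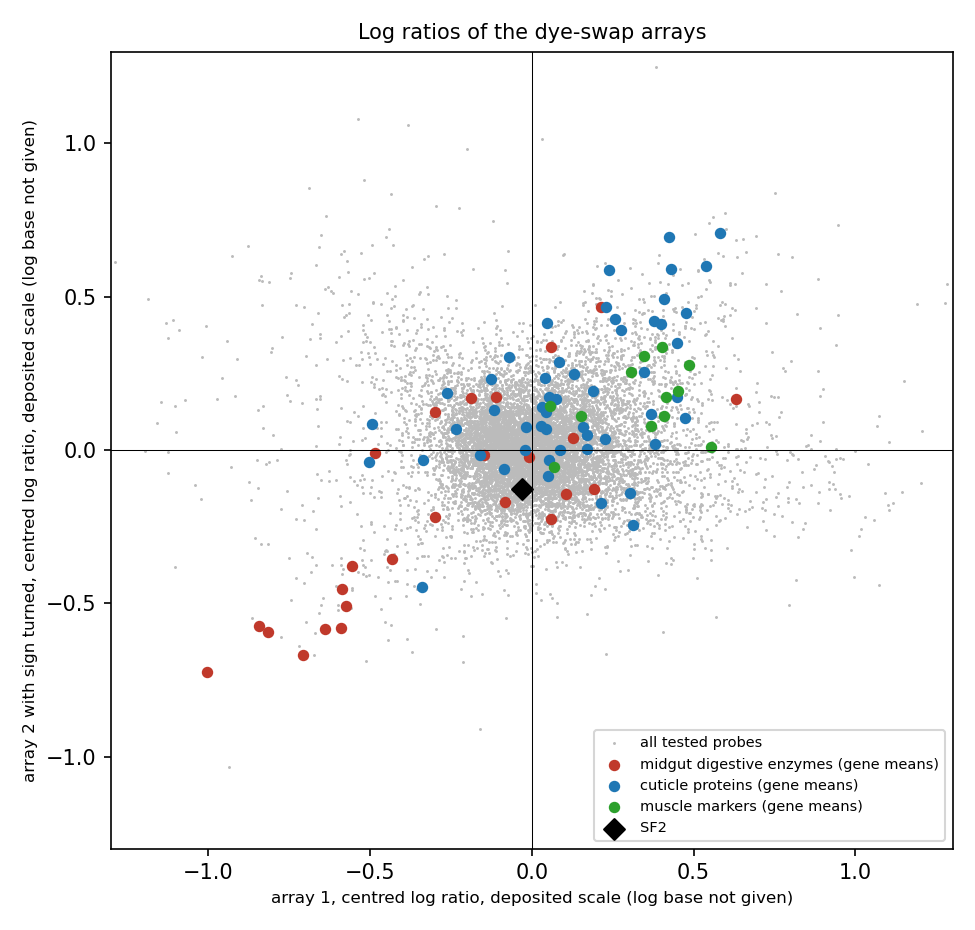
Centred log ratio of array 1 (x axis) against that of array 2 with its sign turned (y axis), both on the deposited scale with the log base not given. Grey points are tested probes (28 lie outside the plotted range), coloured points are gene means of 3 lists and the diamond is SF2. The 10 trypsin and Jonah genes with an adjusted p under 0.05 by limma over the midgut list alone lie at the lower left. Among the other 2 lists, 11 of the 12 muscle genes and 33 of the 52 cuticle genes are positive on both arrays.

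As a group, midgut digestive enzymes were shifted to the negative side (camera at the preset correlation, adjusted p = 1.81e-08). The call was lost with an estimated correlation (camera, adjusted p = 0.662), where 1 residual degree of freedom left little power. The estimate was 0.16, above the preset 0.01. It was also lost with the values read as already running by genotype (adjusted p = 0.709), a reading that called 0 of the 21 lists, so every list shift given here depends on the values running by dye. The list median was -0.126, with array medians of -0.299 and -0.17, and 15 of 25 measured members were negative on both arrays against 4 positive on both. The limma test called 0 members over all genes and 11 adjusted over the list alone, 10 on the negative side and 1 on the positive side. The negative ones were trypsins and Jonah proteases, including alphaTry (-0.467), gammaTry (-0.519) and Jon44E (-0.542), of which epsilonTry was lowest at adjusted p = 0.00344 over the list. The positive one was the amylase gene Amy-d (0.339, adjusted p = 0.0462 over the list alone). The other amylase and maltase genes did not pass and lay on both sides: Mal-A4 had 0.399, Mal-A1 0.197, Mal-A7 0.0835, Amy-p -0.01, Mal-A5 -0.126 and Mal-A6 -0.26. The remaining trypsin and Jonah genes did not pass either. Jon99Fii had -0.247, with -0.483 on array 1 and -0.011 on array 2. The others lay closer to the median: thetaTry -0.087, Jon74E -0.083, deltaTry -0.082, zetaTry -0.02, etaTry -0.0155, Jon99Cii 0.031 and Jon99Ci 0.0315.

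Cuticle proteins, which build the exoskeleton and were not limited to larval ones in this list, were shifted to the positive side (camera, adjusted p = 3.72e-07 at the preset correlation). With an estimated correlation the adjusted p was 0.662. The median was 0.116 (-0.0353 with the values read as already running by genotype), 33 of 52 members were positive on both arrays and 6 negative on both. Over all genes limma called 0 members, and adjusted over the list alone it called 10. Of these, 9 were positive, among them Lcp65Aa and Lcp65Ac (0.569), and Ccp84Ag (-0.394) was negative. Cpr50Cb (-0.272) did not pass. Muscle genes were shifted to the same side (camera, adjusted p = 5.85e-07 at the preset correlation, adjusted p = 0.662 with an estimated one of 0.667). Their median was 0.282 (0.386 on array 1 and 0.16 on array 2), or 1.22-fold on base 2 and 1.91-fold on base 10, and 11 of 12 members were positive on both arrays, with 0 called over all genes and 0 adjusted over the list alone. Tropomyosin 2 (Tm2, 0.382) and the muscle LIM protein gene Mlp84B (0.369) were highest, and the flight muscle actin gene Act88F (0.10) and the titin-like sls (0.007) lowest.

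**Figure D2:**
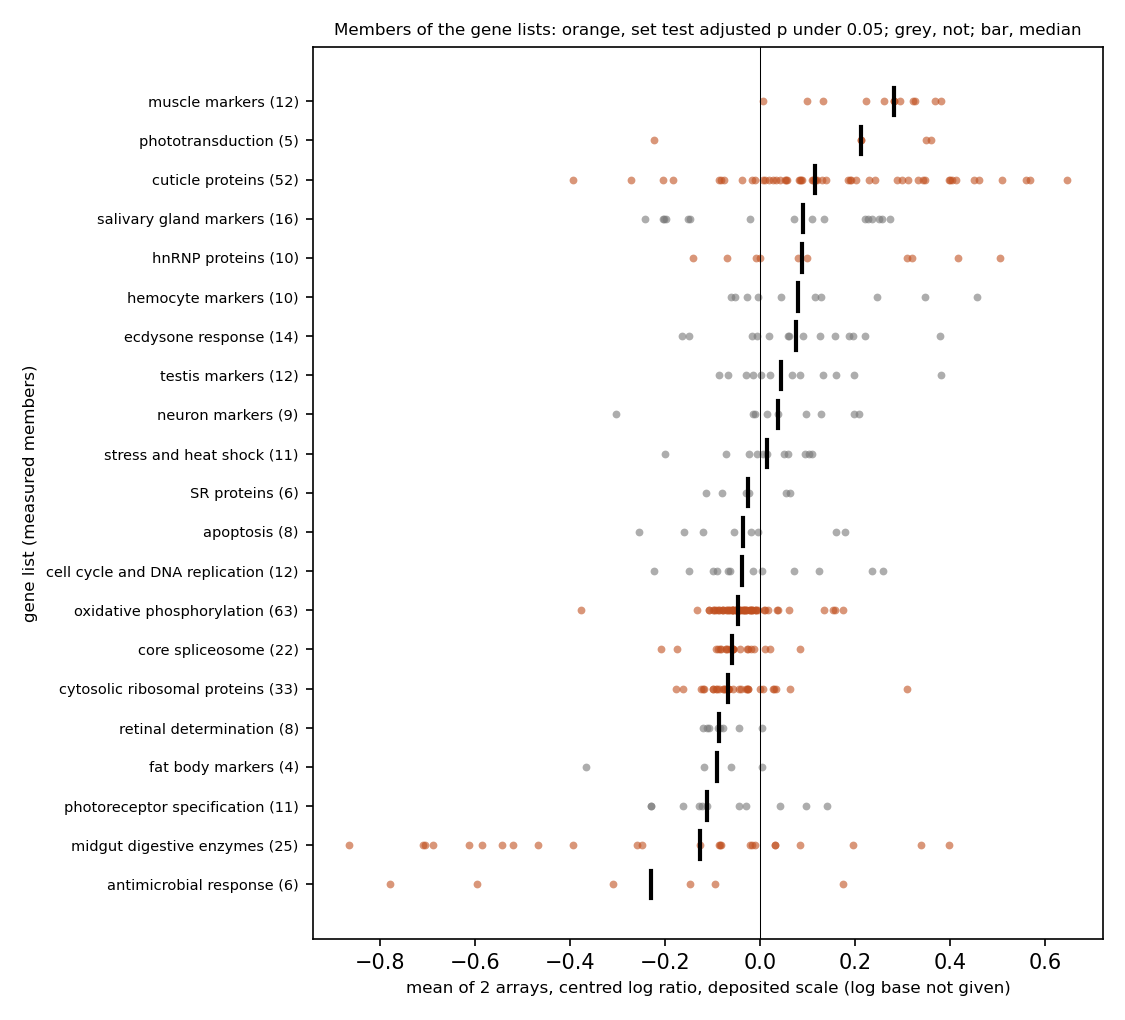
Mean of both arrays (x axis, centred log ratio on the deposited scale, log base not given) for each measured member of the 21 gene lists (y axis, with the number of members), ordered by median. Points are genes, black bars are list medians and orange marks the 9 lists with adjusted p under 0.05 in the set test at the preset correlation, none of which passed with an estimated correlation; medians run from -0.228 for antimicrobial genes to 0.282 for muscle genes.

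Genes of RNA processing were covered by 3 lists. The 6 measured SR protein genes, SF2 among them, had a median of -0.0257 and were not called as a list (adjusted p = 0.547); Srrm1 had 0.0625, tra2 0.056 and Rsf1 -0.113. The hnRNP list, RNA-binding proteins that also act on splice sites, was shifted to the positive side (median 0.0891, adjusted p = 0.0286, and adjusted p = 0.662 with an estimated correlation). Its array medians were 0.142 and 0.0368. It held 2 members that passed over the list alone, smooth (sm, 0.505) and Hrb27C (0.417), while HnRNP-K (-0.0698) and Hrb98DE (-0.141) lay on the other side. The core spliceosome list was shifted slightly to the negative side (median -0.0583, adjusted p = 0.0286, and adjusted p = 0.662 with an estimated correlation), with 15 of 22 members negative on both arrays and 0 called over the list alone. Its lowest members were pea (-0.209) and Prp8 (-0.175), and its highest noi (0.085) and U2A (0.0205).

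Genes of the eye, where GMR is active, were covered by 3 lists, and cell death by 1. Of 21 phototransduction genes only 5 were measured on both arrays, with no opsin gene among them. These 5 were shifted to the positive side (median 0.214, 4 of 5 positive on both arrays, adjusted p = 0.0389, and adjusted p = 0.662 with an estimated correlation). Gbeta76C had 0.361, rdgA 0.349 and Galphaq 0.213, against -0.223 for Ggamma30A, and 0 passed over the list alone. Retinal determination genes had a median of -0.0865 and 6 of 8 members negative on both arrays, but the list was not called (adjusted p = 0.0585); sine oculis (so) had -0.12, tsh -0.111, eya -0.043 and eyg 0.004. Photoreceptor specification genes had a median of -0.112 and were not called either (adjusted p = 0.0972). Their array medians were 0.02 and -0.091, sevenless (sev) had -0.23, salm -0.229, elav 0.141 and B-H1 0.097. The arrays differed in sign for salm (0.03 on array 1 and -0.488 on array 2) and B-H1 (0.273 and -0.079). The apoptosis list was not called (median -0.0363, adjusted p = 0.374), with Buffy at -0.254, Dark at -0.159, skl at 0.18 and Dronc at 0.16.

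Antimicrobial genes were shifted to the negative side (median -0.228, 5 of 6 members negative on both arrays, adjusted p = 0.00389, and adjusted p = 0.662 with an estimated correlation). Array medians were -0.354 and -0.139. Drosomycin (Drs, -0.595) passed over the list alone. Diptericin B (DptB) had a mean of -0.778 that rested mostly on array 1, where it was -1.43 against -0.126 on array 2; Def had -0.094 and AttB 0.175. Cytosolic ribosomal protein genes (median -0.067, 17 of 33 members negative on both arrays, adjusted p = 0.0214) and oxidative phosphorylation genes (median -0.045, 20 of 63 negative on both, adjusted p = 0.0286) were also shifted to the negative side, by little. Neither call held with an estimated correlation (adjusted p = 0.662 and 0.692), and 0 members of either passed over the list alone. The ribosomal medians were -0.105 and -0.038 on the 2 arrays, and the oxidative phosphorylation medians had opposite signs, -0.076 and 0.02. RpL37-2 had -0.176, RpL24-like -0.161, RpL3 0.0643 and RpS19b 0.309. UQCR-11L had -0.376, ND-B14 -0.133, ND-24L 0.159 and UQCR-14L 0.176. The arrays differed in sign for RpL3 (0.195 on array 1 and -0.066 on array 2), RpS19b (0.636 and -0.018) and UQCR-11L (-0.801 and 0.05).

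The other lists were not called, and 0 of their members passed over the list alone. Array medians had opposite signs for ecdysone response (0.165 and -0.0235), salivary gland (-0.032 and 0.11), stress (0.067 and -0.022) and cell cycle genes (0.033 and -0.087). The ecdysone response, the hormonal programme of moulting, had a median of 0.0754 (adjusted p = 0.123), with EcR at 0.38, ImpL1 at 0.222, ImpE3 at -0.149 and ImpE2 at -0.165. Fat body markers had a median of -0.0893 (adjusted p = 0.0642), with apolpp at -0.366, Fbp2 at -0.119, Fbp1 at -0.06 and Lsp2 at 0.0045. Hemocyte markers had a median of 0.0805 (adjusted p = 0.0704), and the prophenoloxidase genes PPO1 (0.457) and PPO2 (0.348) were highest against srp (-0.0615) and Hml (-0.052). Salivary gland markers had a median of 0.0905 (adjusted p = 0.621), with Sgs1 at 0.274 and Eig71Ee at 0.257 against Eig71Ea at -0.243 and Sgs4 at -0.205. Of the 16 measured, 7 were positive on both arrays: Sgs1, ng1, ng2, ng3, Eig71Ee, Eig71Eh and Eig71Ej. Another 6 were negative on both: Sgs3, Sgs4, Sgs5, Sgs7, Sgs8 and Eig71Ea. This split was read from the values and was not tested. Neuron markers had a median of 0.0385 (adjusted p = 0.547), with cpx at 0.209, VAChT at 0.199, nSyb at -0.0135 and unc-13 at -0.302. Testis markers had a median of 0.0438 (adjusted p = 0.357), with Mst77F at 0.381, Mst84Dc at 0.199, aly at -0.068 and Mst84B at -0.086. Stress and heat shock genes had a median of 0.016 (adjusted p = 0.854), with puc at 0.109, Hsp27 at 0.104, Hsf at -0.071 and GstE1 at -0.20. Cell cycle and DNA replication genes had a median of -0.0385 (adjusted p = 0.677), with CycB at 0.26, CycE at 0.236, Mcm2 at -0.149 and E2f1 at -0.224.

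Over all 10912 probes, limma called 0 at an adjusted p under 0.05, with a lowest adjusted p of 0.419. At an unadjusted p under 0.05 it found 730 probes, 519 positive and 211 negative, where 545.6 were expected by chance. With the values read as already running by genotype, the number was 533, with 217 positive and 316 negative. At gene level it called 0 of 9266 genes, with 639 at an unadjusted p under 0.05. Read as log2, 99.3% of probe means lay within 1.5-fold of the array median, 0 probes passed 2-fold on both arrays on the same side and 1 did so on opposite sides. Read as log10, 81.9% lay within 1.5-fold, and 298 probes passed 2-fold on the same side against 175 on opposite sides. At 1.5-fold on base 2 the counts were 22 on the same side, 13 positive and 9 negative, and 10 on opposite sides. The turned arrays were nearly uncorrelated across probes (r = 0.0244, rho = 0.00787; probes are not independent replicates), and 49.1% of probes had the same turned sign. Genes with high values of opposite sign were CG7768 (-4.28 and 1.09), Rab3-GAP (-0.744 and 0.576) and CG9777 (-0.837 and 0.569).

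The 960 repeated unnamed features behaved unlike the other probes. Their deposited values correlated between arrays without turning (r = 0.765 over 692 features measured on both arrays), against -0.0244 for the other probes. The 2 highest and 2 lowest places were taken among those with 24 values on both arrays and a scaled median absolute deviation under 0.1. Medians were 0.972 on array 1 and 1.10 on array 2 at the highest place, 0.191 and 0.31 at the next, -0.676 and -0.584 at the second lowest, and -1.08 and -0.942 at the lowest, where the SD of the copies was 0.184 on array 1 and 0.0415 on array 2. The other 5 such places had medians from -0.268 to -0.0055. A further 8 places had medians from -0.58 to -0.349, with more spread (SD 0.155 to 0.504).

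**Figure D3:**
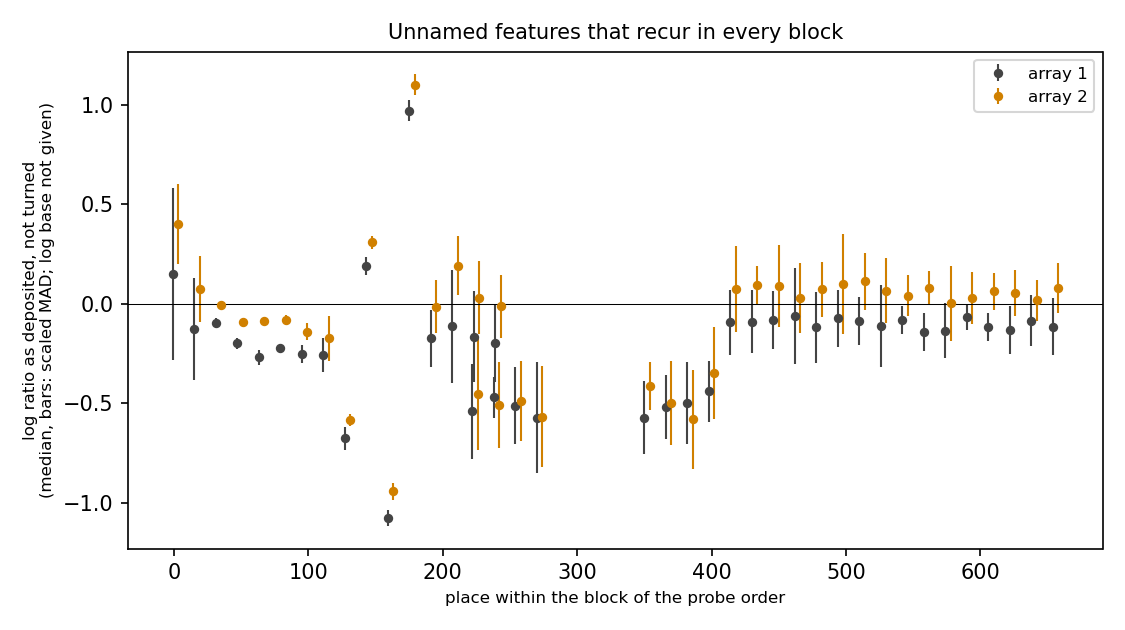
Median deposited log ratio (y axis, not turned, log base not given) of the 24 copies of each unnamed feature against its place within a block of the probe order (x axis), for both arrays, drawn slightly apart. Bars are scaled median absolute deviations; the 4 places whose medians are printed lie between -1.08 and 1.10 on both arrays.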

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

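Tests in this part were chosen after the data had been seen, apart from those planned beforehand. The planned ones are the set tests of the fixed lists on uncorrected values, at a preset or estimated correlation, and the other reading of direction. Probes with a value on 1 array alone did not enter the reported comparison. They entered a limma alternative, which called 0 probes, and the counts made on each array alone. Without the repeated unnamed features, 11.9% of 109 probes measured on array 1 alone lay at least 1 unit (2-fold on base 2) from that array's median, with an exact binomial 95% interval of 6.51 to 19.5%. Among probes measured on both arrays, 0.587% did so on array 1. Of 2582 probes measured on array 2 alone, 0.465% did so (interval 0.240 to 0.810%), against 0.0916% of the probes measured on both. These shares drew attention because they lie in values that the comparison leaves out and stand above the shares of the compared probes. No explanation was tested, and no dye-swapped value exists for these probes.

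The separation of digestive enzymes from cuticle and muscle genes was weighed against technical explanations, with dASF/SF2 against control as the biological one. Spot position is argued against at the preset correlation, where the highest adjusted p of the 3 lists after the probe-order correction was 3.31e-06. The medians went from -0.126 to -0.181 for midgut, stayed at 0.116 for cuticle and went from 0.282 to 0.237 for muscle genes. With an estimated correlation, computed on uncorrected values only, the adjusted p was 0.662 for each. A gene-specific dye effect, if values run by dye, would put a list on opposite turned sides of the 2 arrays. Picked on array 1 alone, 7 of the 21 lists had medians outside percentiles 2.5 to 97.5 of random lists. On array 2 alone, 4 of them lay outside on the same turned side and 0 on the opposite side; the 4 were the 3 lists of the pattern and the antimicrobial list. The other 3 lay within these limits on array 2, where oxidative phosphorylation (-0.076 and 0.02) and the ecdysone response (0.165 and -0.0235) had turned to the opposite side. For these 2 lists the array values leave a dye effect open, but one of equal size on both arrays cancels in the turned mean. If the deposited values already run by genotype, the separation is itself a dye effect: 0 lists were then called, and this reading cannot be told apart from the main one by the labels. A smaller share of midgut alone would raise other tissues alike, but the 7 other tissue lists fixed beforehand differed among themselves (permutation p = 0.00515 over 115 genes, which are not independent). The highest and lowest of them on array 1, muscle and fat body, lay 0.288 apart in the same order on array 2 (two-sided permutation p = 0.00114, 12 and 4 genes). The 7 lists include cuticle and muscle, whose shifts are part of the pattern itself. Both tests therefore give no independent evidence, and they do not exclude a smaller midgut share. Such a share, alone or together with a change in muscle, stays open.

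What stays open includes the genotype, untested beyond these 2 arrays, and a difference in the stage, feeding or tissue mix of the larvae. A difference in moulting stage may move cuticle and digestive genes in this way. The ecdysone response list had an adjusted p of 0.123, and 0.0485 after the probe-order correction, but array medians of opposite signs (0.165 and -0.0235), so stage cannot be told apart from genotype when each genotype may be a single pool.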

How the results depend on the processing

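Over all results and alternatives, 789 values stayed on the same side or within the spread, 59 moved, 27 lost a call, 8 gained one, and 21 correlations, genes or list tests changed sign. A named gene or list test that kept its sign and stayed without a call counts in the first number, however far its size fell. Of the list medians, which have no test and are counted among the first 2 numbers, 15 changed sign, in 10 lists, 7 of them under the other reading of direction. The cause was not tested except where an alternative's construction gives it. With the values read as already turned to genotype, limma still called 0 probes; 1 probe passed 2-fold and 10 passed 1.5-fold on both arrays. That reading turned r to -0.0244, rho to -0.00787, SF2 to 0.0485, hlk to -0.043, sona to -0.0025, Actn (the named probe) to -0.027, CG8319 to -0.626, Pglym78 to -0.0595, CG32241 to -0.0215, Lcp65Aa to -0.0635 and CG6271 to 0.0495. The others of the 24 strongest genes kept their sign but came close to 0: CG12896 was highest at 0.106, epsilonTry lowest at -0.14, and Jon65Aiii had -0.0185. Of 86 further genes under the naming rule, 37 changed sign in that reading, with values from -2.68 (CG7768) to 0.327 (RpS19b); under the other scalings and probe sets 0 to 5 did, with 1 array alone 9 to 11. It called 0 lists, with adjusted p of 0.826 for hnRNP, 0.709 for core spliceosome, 0.975 for phototransduction, 0.668 for antimicrobial, 0.613 for ribosomal, 0.102 for oxidative phosphorylation, 0.613 for muscle, 0.709 for midgut and 0.709 for cuticle genes, the last with the opposite sign. Lists not called in either reading also changed sign: photoreceptor specification and cell cycle (0.668 each), apoptosis (0.876), fat body (0.975), salivary gland (0.709) and neurons (0.899), and cell cycle by fry (0.999).

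The limma count was 19 by a plain t statistic with 1 degree of freedom after adjustment, which has no shared variance (605 unadjusted), and 730 at an unadjusted p under 0.05. Of the alternatives chosen after seeing the data, named probes with arrays centred on all features gave 1 call, CG6271 (-0.982, adjusted p = 0.0384), and 80 at an adjusted p under 0.1; probes with 1 gene name, a smaller set that was centred without the repeated features, gave 0. The remaining planned and added alternatives also gave 0: no centring, equal spread, quantile, robust prior, adjusted p under 0.1, gene means, exact zeros left out, repeated features kept, probe-order correction, the other log bases and probes measured on 1 array. Keeping the repeated features turned r to -0.154 and rho to -0.0612, and counted 24 probes at 1.5-fold on the same side against 92 on opposite sides, of which 83 were repeated features. Named probes alone gave r = 0.0791 and rho = 0.0296 (0.081 and 0.0309 centred on all features), and the probe-order correction 0.148 and 0.144.

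Size counts follow the base by construction. On base 10, 298 probes passed 2-fold and 811 passed 1.5-fold on the same side, with 81.9% within 1.5-fold; on the natural log these were 4, 124 and 97.1%. On base 2 the 1.5-fold rule gave 22. With 1 array alone, which leaves dye bias unbalanced and allows no test, 22 to 77 probes passed 2-fold and 96.3 to 99.1% lay within 1.5-fold, counted over every probe with a value on that array; among the 10912 tested probes 10 to 64 passed 2-fold. SF2 was -0.128 to -0.031.

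The number of lists called went from 9 to 14 with the probe-order correction and to 0 with an estimated correlation and with fry. It was 8 with equal spread, where oxidative phosphorylation missed the threshold (adjusted p = 0.0503), 11 with quantile normalization and 9 under the other scalings. With an estimated correlation the adjusted p was 0.662 for each of the 9 lists but oxidative phosphorylation (0.692). By fry it was 0.377 for hnRNP, 0.424 for core spliceosome, 0.165 for phototransduction, 0.437 for antimicrobial, 0.490 for ribosomal, 0.641 for oxidative phosphorylation, 0.424 for muscle, 0.346 for midgut and 0.333 for cuticle genes. Both tests have 1 residual degree of freedom and little power, so these losses cannot decide whether the lists shifted. Estimated correlations were 0.667 for muscle, 0.333 for antimicrobial, 0.289 for hnRNP, 0.263 for oxidative phosphorylation and 0.242 for ribosomal genes. They were 0.16 for midgut, 0.0909 for core spliceosome, 0.0769 for cuticle and -0.2 for phototransduction genes, against the preset 0.01. The estimates are imprecise, but where the correlation exceeds the preset, p-values at the preset are too small. Lists gained were retinal determination (0.0487) and fat body (0.0492) under quantile normalization, and both of these, photoreceptor specification, ecdysone response and hemocytes under the probe-order correction (0.0386 to 0.0485). Background correction, a filter on dim probes and a slide block were not run, since the table used here holds no intensities or slides. No paired analysis was possible because the arrays form a single group of ratios.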

Other observations

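All tests in this part were chosen after the data had been seen. Grouping genes by the leading letters of their symbols gave 61 families with at least 8 measured genes, and 3 were called by camera at the preset correlation. The Jonah proteases (Jon) had a median of -0.468, with 7 of 10 genes negative on both arrays and 0 positive on both (adjusted p = 3.19e-09). Cuticle genes of the Cpr family had a median of 0.114, with 26 of 40 positive on both arrays (adjusted p = 2.76e-05). The yellow family, which includes genes of cuticle pigmentation, had a median of 0.182, with 6 of 10 positive on both arrays and 0 negative on both (adjusted p = 0.000275). Its highest members were yellow-d2 (0.654) and yellow-e (0.455), and its array medians were 0.343 and 0.106. With an estimated correlation 0 of the 61 families were called (adjusted p = 0.940 for each of these 3), and Jon and Cpr overlap the fixed midgut and cuticle lists.

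Probes of one gene shared the turned difference. Over 381 genes with several probes (857 probes), the intraclass correlation of the turned mean was 0.266, above the highest of 1000 shuffles (0.145; permutation p = 0.000999, the smallest these shuffles can give). For the mean as deposited, without turning, it was 0.0251. This is consistent with probes of one gene reporting the same transcript in the turned direction, and it is a hypothesis in favour of values that run by dye. Probes placed near each other on the array were not separated in this test. The repeated unnamed features, in contrast, correlated between arrays without turning (r = 0.765). They do not settle the reading of direction either, for the reason given next.

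The repeated unnamed features with the 2 highest and 2 lowest medians printed in the report may be spike-in RNAs mixed at 10:1, 3:1, 1:3 and 1:10, as sold for two-colour arrays. The labels do not say so, and the ratios are assumed. The gap between the highest and lowest place was 2.05 as a mean of both arrays, and that between the next pair 0.88. Such ratios would give 2 and 0.954 on a log10 scale, but 6.64 and 3.17 on a log2 scale. The levels fit less well than the gaps. The outer pair was centred at -0.052 on array 1 and 0.0803 on array 2, the inner pair at -0.243 and -0.137, so that no single offset brings both pairs to the assumed ratios. The test therefore leaves the hypothesis open. If it holds, the deposited values are log10 and the folds on base 10 apply. No source used here names the features or the base. The highest and lowest places kept their side on both arrays without turning. RNAs added by genotype would do so if the values already run by genotype, and RNAs added by dye if they run by dye. How such RNAs were added is not given, so these features leave the reading of direction open.

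Named and unnamed probes outside the repeated places still followed the probe order. The mean as deposited correlated at 0.322 with the probe 16 places on, and the turned mean at 0.0995; after the probe-order correction these were 0.0659 and 0.00568. The 5 named probes with a mean over 1 unit (2-fold on base 2), picked after their values were seen, rested mostly on 1 array in 4 cases: CG3706 (-3.58 and 0.096), Upf3 (-2.66 and -0.038), SkpC (-0.001 and 2.85) and CG7768 (-4.28 and 1.09). The other was CG8319 (0.608 and 1.86). Sxl, of the sex-biased list, had 0.319 and 0.004.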
